A study of Homo sapiens with 210 samples.

How the data were processed

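The material was RNA-seq and CUT&RUN of HCT116 cells from 3 experiments. The deposited gene and peak tables hold counts made with featureCounts, per the file headers, version 2.0.6 for the RNA of experiment 1 and 2.0.8 otherwise, and the bed lists of merged peaks carry a score the authors gave without stating its meaning. RNA read pairs were counted without strand in experiments 1 and 2, and the headers for RNA of experiment 3 show no strand or pair option although the tables are named as reverse-stranded, so whether strand was used there is open. Without strand, a gene overlapping another on the opposite strand, such as TENM3, PRKCQ, RUNX2, ACSL5, CDKN1A or VIM, could not be told from it. Peak tables of experiment 3 were counted with overlaps allowed and duplicates ignored, per the file headers, and some headers stop before these options. Trimmomatic, FastQC, MultiQC, Bowtie2, STAR, Picard, bedtools, featureCounts, SAMtools and MACS3 were used with the hg38 build, per the submitters' processing notes, which list the tools without versions or settings.

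Peak tables also hold stretches between peaks. These took 36.9% to 99.8% of the reads of the antibody libraries in use, were kept out of library sizes and tests, and served only for the share of reads in peaks and for whole-library totals. No column was left unmapped. The labels give a batch number that matches experiments 1 and 2 and none for experiment 3, and every comparison stayed within 1 experiment. Left out of the comparisons, as the labels mark them unused, were L307R replicates 3 and 4 and WT replicates 5 and 6 of the CUT&RUN of experiment 1 and total RNA of WT replicates 9 and 10. Left out alike were KO and LENTI replicates 3 and 4, WT replicates 7 and 8 and WT EZH2 replicates 3 and 4 of the CUT&RUN of experiment 2, which no table holds. IgG libraries in use held 945942 to 20424429 counts.

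The comparisons were L307R against WT, KO against WT, LENTI against KO and BRM014 against WT, 4 for RNA and 25 for CUT&RUN. Each table was fitted once with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with all its groups sharing one spread. CPM of genes were scaled with the TMM factors, CPM of single PHC2 libraries with the library total, and CPM of peaks with the whole library. Standard errors were the log2 change divided by the root of F. Where a group had 0 counts the change is a lower bound with a floor of 3 counts over the group. Bounds and intervals cover counting error only. With changes simulated in 200 features per table, 2-fold ones were recovered for RNA in 98.5% (L307R), 95.5% (KO) and 93.8% (BRM014). For peaks it was 11.5% for PHC2 L307R and in KO PHC2 0%, RING1B 24.6%, H3K27me3 45.9%, H3K27ac 86.4%, BAF155 42.4% and EZH2 5.08%. Experiment 3 gave PHC2 KO 35.5%, PHC3 and EED KO 33.3% and SMARCC1 64.1%. None reversed, and many 2-fold peak changes would go uncalled. The simulation used a single dispersion and fewer features than the real fits, which may recover less.

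Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation), adjusted over the lists of each comparison. The 26 lists were PRC1, PRC2 and SWI/SNF subunits, HOX genes, developmental regulators, p53 targets, S phase, G2/M, Wnt and intestinal stem, intestinal differentiation, epithelial junction, mesenchymal, immediate-early and AP-1, interferon response, NF-kB inflammatory, hypoxia, cholesterol synthesis, stress response (ATF4 and UPR), ribosomal protein, mitochondrially encoded (0 members measured in any table), replication-dependent histone, non-polyadenylated small RNA, cancer-testis antigen, neuronal, fibroblast and blood cell genes. Site genes made 28. PRC1 and SWI/SNF sites were the 10% of RING1B and of BAF155 (SMARCC1 in experiment 3) peaks with the highest mean log2 ratio to IgG over all groups, with experiment 2's RING1B used for experiment 3, and overlap meant at least 1 bp. Genes were assigned to peaks within 2 kb of a start. The lists, site sets and comparisons, and the alternatives below that are not named as added, were fixed before the data were examined. Named genes were PHC2, the 10 largest rises and falls (called, mean of at least 1 CPM, protein coding), up to 4 members of each list with the smallest adjusted p and all called subunits, and for peaks the 3 largest rises and falls per comparison at or above the median level, named by the nearest protein-coding start. Genes that fell out of a call without 1 library were mostly passed over for the next, and the loci with summed levels were chosen after their values were seen.

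Alternatives were RLE factors, column totals, no filter, DESeq2 1.42.0, leave-one-out fits, the replicate number as a block, unused libraries added, TMM on the 25% of peaks nearest IgG, and, added after the data were seen, whole-library totals, unused libraries alone, a term for RNA replicates 1 to 3 or 4 to 6, each of these replicate sets alone, LENTI replicates 1 and 2 or 3 and 4 alone, list tests with the block or the term, and overlaps of DESeq2 calls. Only in RNA L307R did replicate numbers pair by the rule fixed in advance (same-number correlations of residuals 0.124 to 0.292, all over 0.1, other pairs -0.35 to 0.446, 3 of 6 best with their own number). The number comes from the labels, which put all 12 libraries in the same batch. The correlation followed the standing apart of replicates 1 to 3 and 4 to 6. No 2 libraries of a group were closer than counting noise allows (chi-squared per degree of freedom 1.63 at least). CUT&RUN pairs lay at 1.63 to 2.59 and RNA pairs at 1.88 to 21.4. The CUT&RUN libraries of a group thus differed by little beyond counting noise, and their p-values rest on that small spread. Dixon's test, which marks about 1 group in 20 by chance, found no stray library in the 4 RNA groups of 4 or more libraries, the only ones it was run on. Overlaps used Fisher's exact test and 10000 permutations, with bedtools 2.31.1 and GenomicRanges 1.54.1.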

Results

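Gene expression and chromatin occupancy were measured in HCT116, a human colon cancer line, by RNA sequencing and by CUT&RUN, in which an antibody-tethered nuclease releases DNA fragments at the sites a protein or histone mark occupies. The cells differed in PHC2, a subunit of the Polycomb repressive complex PRC1 whose SAM domain polymerises, or in the activity of SWI/SNF, a chromatin remodelling complex. In experiment 1, cells with the PHC2 substitution L307R were set against WT, with 6 RNA libraries per group (total RNA after ribosomal depletion) and 2 libraries per group and antibody in use (PHC2, RING1B, H3K27me3, H3K27ac, BAF155 and IgG). In experiment 2, WT, PHC2 knockout (KO) and knockout cells carrying a PHC2 lentivirus (LENTI) had 2, 4 and 4 poly(A) RNA libraries and 2 CUT&RUN libraries per group and antibody in use, with EZH2 added. In experiment 3, PHC2 was profiled in WT, KO, LENTI and BRM014-treated cells, PHC3 and EED in WT, KO and LENTI, and SMARCC1 in WT and BRM014, with 3 libraries each. The labels give the LENTI samples of experiment 3 only a knockout genotype and the lentivirus in their titles, and the series text lists SMARCA1 where the samples say SMARCC1. RNA of experiment 3 came from 3 BRM014 and 3 WT poly(A) libraries. BRM014 inhibits the ATPases of SWI/SNF, and BAF155 is the protein of the gene SMARCC1. The questions were how loss of PHC2 or of its polymerising surface alters Polycomb occupancy, SWI/SNF occupancy and transcription. Others were whether PHC2 overexpressed from a lentivirus in knockout cells alters them again, and what SWI/SNF inhibition does. RNA libraries held 5984854 to 9642059 counts in experiment 1, 13276152 to 17886187 in experiment 2 and 4891143 to 7093446 in experiment 3. The antibody libraries in use held 4119107 counts (EED) to 44118388 (H3K27me3). The p-values measure only the spread between these libraries, since nothing in the labels says whether they came from separate cultures. CUT&RUN changes were scaled on reads in peaks, so they are relative to the typical peak of their table, and calls on whole-library totals are given where the split of a table moves.

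PHC2 itself (chromosome 1, 33323626 to 33431095, hg38) was counted in every RNA library. It stood at 51.3 to 64.0 CPM, counts scaled to the library total, in the 6 L307R libraries and 66.1 to 89.7 in the 6 WT libraries of experiment 1, a fall by 0.45 on the log2 scale (SE 0.0806, edgeR adjusted p = 0.00495). In experiment 2 it stood at 207 and 203 CPM in WT and 113 to 119 in the 4 KO libraries (log2 change -0.81, SE 0.074, edgeR adjusted p = 9.12e-06), so the knockout lowered the transcript and did not remove it. The LENTI libraries held 131, 131, 108 and 105 CPM, and their mean of 117 ± 12.1 (SD, n = 4) did not differ from KO (log2 change -0.01, edgeR adjusted p = 0.957). LENTI replicates 1 and 2 alone were above every KO library (log2 change 0.13) and replicates 3 and 4 below every one. Nothing in the labels says which part of the gene the edit or the insert covers. BRM014 lowered PHC2 from 290 ± 5.92 to 158 ± 5.01 CPM (n = 3, log2 change -0.88, edgeR adjusted p = 5.02e-08).

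PHC2 protein at its peaks was far lower in L307R cells. The PHC2 peaks held 15.1% ± 2.36 (SD, n = 2) of the reads of WT PHC2 libraries, 6.85 times the share of the WT IgG libraries, and 4.13% ± 0.743 in L307R, 1.55 times IgG. At PRC1 sites, the 10% of RING1B peaks with the highest RING1B over IgG, the share went from 1.11% (9.08 times IgG) to 0.336% (2.63 times). Relative to the typical peak, 1575 of 39312 PHC2 peaks changed by edgeR, 237 up and 1338 down, and the falls with the highest bounds were pericentromeric on chromosome 2, such as 92212399 to 92213039, which lay between genes and was at least 45.8-fold lower (0 against 194 counts, floor 3 counts over the group). A peak 12.9 kb from CBX8, a PRC1 subunit gene, on chromosome 17 (79809951 to 79810682) rose relative to the others (log2 change 2.03, edgeR adjusted p = 5.28e-05). On whole-library totals it was higher by 0.37, short of the test. On those totals all 30106 called peaks were lower and the median peak stood at -1.67 on the log2 scale. Column totals gave 495 up and 828 down and TMM on the 25% of peaks nearest IgG 729 and 688. Of 67 PHC2 peaks at SWI/SNF sites 6 rose and 1 fell (median 0.64, -1.03 on whole-library totals; camera on edgeR counts, adjusted p = 2.25e-07, adjusted p = 0.0874 with an estimated correlation). PRC1 sites had 29 rises and 91 falls of 2801 (median 0.08, -1.58 on whole-library totals; adjusted p = 0.311). The count was 2898 without L307R replicate 2, 684 without WT replicate 1 and 615 without WT replicate 2.

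RING1B, the ubiquitin ligase of PRC1, was also lower over its peaks in L307R cells, at 9.29% ± 0.708 of reads against 18.7% ± 0.139 in WT (2.38 and 5.64 times IgG, n = 2). Relative to the typical peak 14411 of 69488 RING1B peaks changed by edgeR, 8256 up and 6155 down. Peaks in RMST, a long noncoding RNA gene on chromosome 12, held the largest rises (97560125 to 97560916, exonic, log2 change 4.95, edgeR adjusted p = 8.64e-12). A pericentromeric peak of chromosome 2 (94009312 to 94009816) was at least 31.7-fold lower. Among promoter peaks of HOX genes, which pattern the body axis, 9 of 16 rose. Of 36 at other developmental regulators 16 rose, but both groups flip on whole-library totals, with medians of -0.26 and -0.23, 2 HOX peaks lower, and 3 developmental peaks higher and 9 lower. At SWI/SNF sites, the 10% of BAF155 peaks with the highest BAF155 over IgG, 290 of 462 RING1B peaks rose and 5 fell (median 1.21 against -0.02 elsewhere; camera on edgeR counts, adjusted p = 1.37e-29, adjusted p = 0.0697 with an estimated correlation). PRC1 sites had a median of 0.18 over 7041 peaks (-0.75 on whole-library totals, camera on edgeR counts, adjusted p = 0.15). On whole-library totals SWI/SNF sites kept a median of 0.28 (89 up, 38 down) against -0.95 for all peaks (1948 up, 34380 down). IgG in BAF155 peaks was higher too (4.95% in L307R, 4.26% in WT), so background may lie behind the 0.28. TMM on the 25% nearest IgG gave 10640 up and 4403 down. Adding unused libraries gave 6323 calls. The count was 9274 without WT replicate 1 and 8615 without WT replicate 2.

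**Figure D1:**
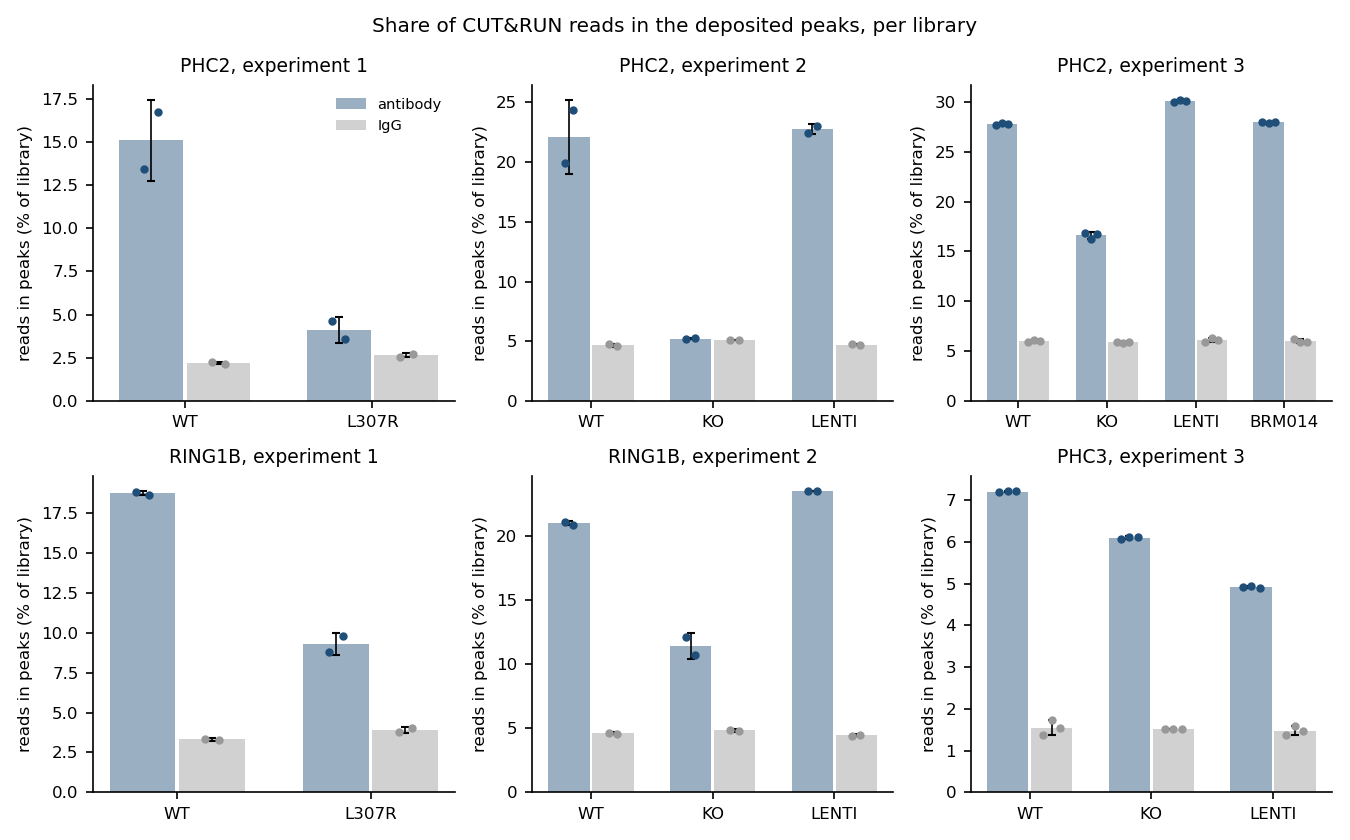
Percentage of reads inside the peaks for PHC2, RING1B and PHC3, one panel per antibody and experiment, with a point per library, bars at the mean, SD, and IgG libraries counted in the same peaks. PHC2 stood at 15.1% in WT and 4.13% in L307R, and at 22.1%, 5.22% and 22.8% in WT, KO and LENTI of experiment 2.

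H3K27me3, the mark laid down by PRC2, was redistributed between loci in L307R cells while its total share barely moved (59.8% ± 0.00105 of reads in WT, 57.5% ± 0.179 in L307R, n = 2). It was lost over a set of genes that included TENM3, a teneurin of neurons, where the summed peaks held 1250 ± 20.5 CPM in WT and 86.4 ± 2.06 in L307R (IgG 164 and 201) and 169 of 178 peaks fell, and over EPHA4, an ephrin receptor, with 437 ± 5.01 and 42.2 ± 1.55 CPM and all 50 peaks lower. ZBTB18, a transcriptional repressor, went from 155 ± 2.12 to 13.7 ± 0.624 CPM, and the sodium channel SCN9A from 117 ± 2.87 to 14 ± 0.774. A peak 151 kb from EYA4 in LINC00326 (chromosome 6, 133087733 to 133089232) was at least 81.9-fold lower (0 counts). A peak between genes 625 kb from NR2F2 (chromosome 15, 96951507 to 96953247) rose by 5.17 (log2, edgeR adjusted p = 4.56e-26). In all, edgeR called 36117 of 135707 peaks higher and 42057 lower. At PRC1 sites 1602 rose and 2386 fell of 5454 (median -0.17, camera on edgeR counts, adjusted p = 0.00679, adjusted p = 0.0697 with an estimated correlation). 55 rose and 25 fell of 133 at SWI/SNF sites (adjusted p = 0.268). With the unused libraries added 28757 peaks were called. With TMM on the 25% of peaks nearest IgG the calls were 85898 up and 17284 down, since the median peak then stood 1.23 higher.

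H3K27ac, a mark of active promoters and enhancers, held 17.8% ± 1.88 of reads in its peaks in L307R and 23.7% ± 0.709 in WT (n = 2), but 10.5% and 9.95% in the unused libraries. 1496 of 22417 peaks rose and 2576 fell by edgeR. With the unused libraries added only 3 peaks were called. In the libraries in use, the largest fall was a peak between genes 129 kb from SOCS6 (chromosome 18, 70418519 to 70425435), at 4.46 CPM in L307R and 47.9 in WT (log2 change -3.03, edgeR adjusted p = 1.15e-169), which stood at 0.10 in the unused libraries alone. The largest rise was an exonic peak of CYB5R2 (chromosome 11, 7672806 to 7674816, log2 change 2.17, edgeR adjusted p = 4.04e-30). At SWI/SNF sites 121 of 1551 peaks rose and 286 fell (camera on edgeR counts, adjusted p = 0.0648), and at PRC1 sites the median was 0.16 (-0.23 on whole-library totals; adjusted p = 0.0664). The count was 2565 without WT replicate 1 and 2078 without WT replicate 2. The split moved to 340 up and 1296 down with DESeq2, to 137 and 7385 on whole-library totals (median -0.38) and to 5017 and 1683 with TMM on the 25% nearest IgG.

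BAF155 rose over TENM3, which had lost H3K27me3 in L307R cells. It held 13.7 ± 0.379 CPM in L307R and 1.75 ± 0.178 in WT, and 7 of 8 peaks rose. Intronic RERG (chromosome 12, 15164186 to 15165112; a RAS-like GTPase) rose by 4.55, a peak 7.28 kb from BMP5, a secreted morphogen, by 4.37, and one 0.681 kb from COL8A1, a collagen, by 3.81. An intronic NXPE2 peak near NXPE1 (chromosome 11, 114562341 to 114563729) fell by 3.75 and an intronic MTUS1 peak by 2.24, but they stood at 1.10 and 0.38 in the unused libraries alone, and the first at 0.09 with these added. With them added 32 BAF155 peaks were called. Of 48543 peaks, edgeR called 709 up and 470 down. 12 of 112 peaks at PRC1 sites rose and 1 fell (median 0.13, -0.11 on whole-library totals; camera on edgeR counts, adjusted p = 0.00114, adjusted p = 0.077 with an estimated correlation). At SWI/SNF sites 86 rose and 24 fell of 4835, against 46 and 91 on whole-library totals (adjusted p = 0.44). The count was 2134 without L307R replicate 1, 2115 without L307R replicate 2, 394 without WT replicate 1 and 329 without WT replicate 2. The split was 329 up and 1317 down on whole-library totals (median -0.24) and 696 and 251 with TMM on the 25% nearest IgG.

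**Figure D2:**
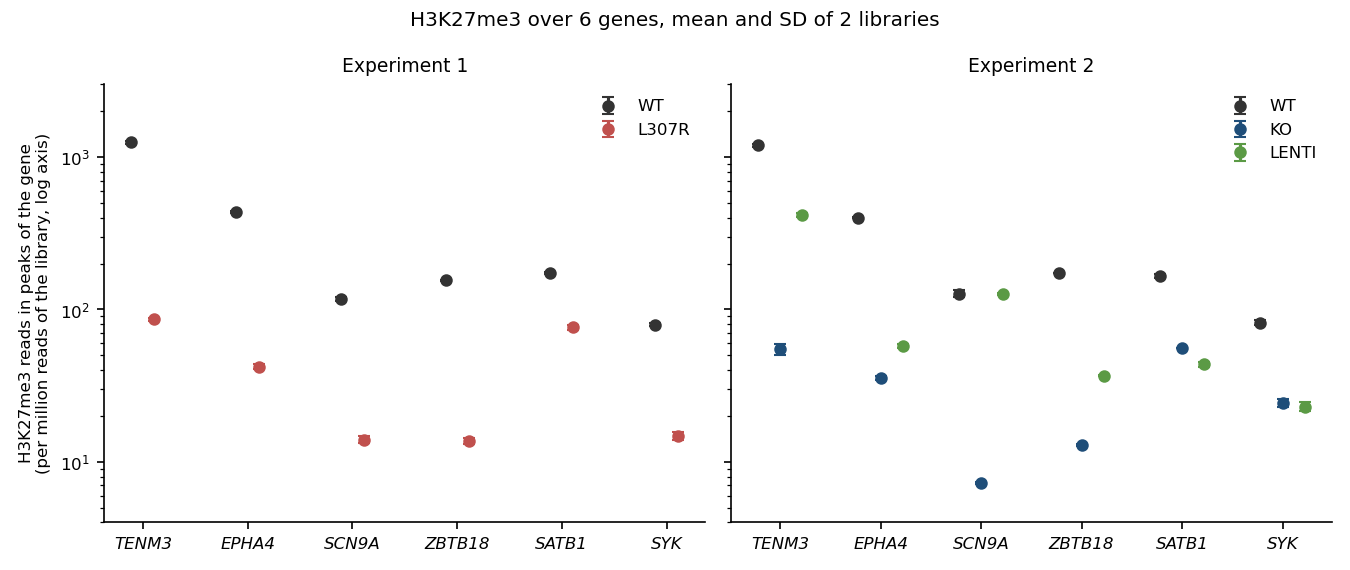
Summed H3K27me3 reads (per library size) over the peaks of 6 genes, mean and SD of 2 libraries per group on a log axis, for experiments 1 and 2. Over TENM3, L307R stood at 86.4 and WT at 1250 in experiment 1, and KO at 54.8, LENTI at 420 and WT at 1200 in experiment 2.

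Transcription rose at several genes that lost H3K27me3 in L307R cells. TENM3 (chromosome 4, 181447613 to 182803024) had 58.1 ± 33.1 CPM in L307R and 0.622 ± 0.427 in WT (SD, n = 6; log2 change 6.60, SE 0.513, edgeR adjusted p = 1.09e-06), counted without strand and so together with TENM3-AS1. EPHA4 rose from 2.40 ± 0.256 to 14.7 ± 1.56 CPM (log2 change 2.62, edgeR adjusted p = 2.63e-08). ZBTB18 rose by 2.98, the tyrosine kinase SYK by 2.63, the kinase DCLK1 from 12.5 to 68.8 CPM, the calpain family member CAPN6 by 3.22, protein kinase C theta (PRKCQ, with its antisense gene) by 2.81, and PELI2, MBNL3 and SNTB1 by 2.55, 2.54 and 2.53. EHF, an ETS factor of epithelia, fell from 3.54 to 0.43 CPM (log2 change -3.01, edgeR adjusted p = 4.85e-06), S100A14 from 53.2 to 14.5 CPM. The sulfotransferase HS3ST1 fell from 65.7 to 24.8 CPM, MGAT4C by 2.08, ZNF850 by 2.03, ANKRD29 by 1.54, SCG2 by 1.46, GGT1 by 1.36 and ANXA10 by 1.28. In all 216 of 14097 genes rose and 159 fell by edgeR. Replicates 1 to 3 and 4 to 6 stood apart within both genotypes. A fit within each called 552 up and 753 down in replicates 1 to 3 and 872 and 992 in replicates 4 to 6. PHC2 fell by 0.35 in the first and 0.55 in the second, and TENM3 rose by 7.53 and 5.16. Over all genes 129 rose in both sets, 162 fell in both and 142 were called in opposite directions. With the replicate number as a block 346 genes rose and 438 fell. The count was 243 without WT replicate 1, 237 without WT replicate 4 and 240 without WT replicate 6.

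Of the lists fixed in advance, mesenchymal genes rose together in L307R, with 5 of 16 up (9 adjusted over the list alone; median 0.50, camera on edgeR counts, adjusted p = 1.86e-07, and 0.0193 with an estimated correlation, but 0.121 with the block besides), among them the matrix proteins FN1 (0.76) and THBS1 (0.81) and the matricellular CCN2 (1.18) and CCN1 (0.86). Epithelial junction genes fell in 2 of 24 cases (5 over the list alone; camera adjusted p = 2.46e-06, adjusted p = 0.328 with an estimated correlation), CLDN7 by 0.59. Cholesterol synthesis genes fell in 3 of 24 (11 over the list alone; camera adjusted p = 1.83e-08, adjusted p = 0.129 with an estimated correlation, but 0.0313 with the block besides), with the epoxidase SQLE down by 0.67 and HMGCS1 by 0.35. Of 29 p53 targets 1 rose and 3 fell (1 and 5 over the list alone; camera adjusted p = 0.00019, and 0.0479 with an estimated correlation, but 0.137 with the block besides), the cell cycle inhibitor CDKN1A by 0.64. Among Wnt and stem genes MYC fell by 0.56 (edgeR adjusted p = 3.29e-05) and 2 of 15 rose. Among SWI/SNF subunits the ATPase SMARCA2 rose from 7.93 ± 1.26 to 19.2 ± 5.99 CPM and 1 of 25 fell. Of 23 PRC1 subunits 1 rose and PHC2 fell. HOX genes had 1 rise of 24, HOXB9 by 0.58 (camera adjusted p = 0.0202, adjusted p = 0.328 with an estimated correlation). Developmental regulators had 1 rise of 36, RUNX2 by 1.17, G2/M genes 1 of 30 (7 up and 1 down over the list alone; camera adjusted p = 0.00138, adjusted p = 0.507 with an estimated correlation) and histone genes 1 of 33, H2BC13. S phase genes had 1 fall of 30, immediate-early genes 1 of 22, PHLDA1 by 0.64. Interferon genes had 1 rise of 22, SAMD9 by 1.03, stress response genes 1 rise (SESN3, 1.49) and 1 fall of 22, and neuronal genes 1 rise (MAP2, 1.94) and 1 fall (SCG2) of 7. In the other 9 lists with measured members (PRC2, hypoxia, NF-kB, intestinal differentiation, ribosomal, small RNA, cancer-testis, fibroblast and blood cell genes, 100 genes) edgeR called 0, against 20 at an unadjusted p under 0.05 and 5 called by DESeq2. The ribosomal list's camera adjusted p was 0.00958 (adjusted p = 0.328 with an estimated correlation). Genes with a PRC1 site within 2 kb of their start, a list chosen on these samples and so not independent evidence of its direction, had 10 rises and 1 fall among 90 (15 and 1 over the list alone; camera adjusted p = 3.45e-06), and those with a SWI/SNF site 4 and 7 of 540. A PHC2 peak lay within 2 kb of the start of 33.3% of 210 genes that rose, 1.4% of 143 that fell and 2.56% of the others. H3K27me3 peaks lay at 29.5%, 2.1% and 2.72%. Genes silent in WT could only rise, so part of this excess is built in and was not tested.

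Knockout of PHC2 took the PHC2 signal of experiment 2 to the IgG level, at 5.22% ± 0.0273 of reads in KO (1.02 times IgG) against 22.1% ± 3.13 in WT (4.73 times), and LENTI libraries were back at 22.8% ± 0.4 (4.82 times, n = 2). Relative to the typical peak 652 of 92674 PHC2 peaks rose and 4714 fell in KO by edgeR, and 3705 rose and 2119 fell in LENTI against KO. Among PRC1 sites 853 of 6050 fell and 26 rose in KO (median -0.51, camera on edgeR counts, adjusted p = 1.24e-05, adjusted p = 0.0571 with an estimated correlation). 565 rose and 73 fell in LENTI (median 0.40, adjusted p = 0.00083, adjusted p = 0.0697 with an estimated correlation). SWI/SNF sites had 16 falls of 167 in KO (adjusted p = 0.0319, adjusted p = 0.335 with an estimated correlation) and 4 rises and 13 falls in LENTI (median -0.57, 1.21 on whole-library totals; adjusted p = 5.18e-06, adjusted p = 0.107 with an estimated correlation). A pericentromeric peak of chromosome 2 (92244161 to 92245052) was at least 30.5-fold lower in KO, and an intronic CFAP299 peak (chromosome 4, 80465200 to 80466818) at least 26.7-fold higher in LENTI. On whole-library totals the calls were 42 up and 53416 down in KO (median -1.77) and 58144 up and 137 down in LENTI (median 1.94). Column totals gave 2025 up and 1436 down in KO and 1511 and 3671 in LENTI, DESeq2 1869 and 2262 in LENTI, and TMM on the 25% nearest IgG 1023 and 2656 in KO. The KO count was 3307 and 3389 without LENTI replicates 1 and 2 and 2947 and 2678 without WT replicates 3 and 4, and the LENTI count 2305 and 2191 without LENTI replicates 1 and 2 and 3807 and 3804 without WT replicates 3 and 4.

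RING1B followed PHC2 in total, at 21% ± 0.146 of reads in WT, 11.4% ± 1.01 in KO and 23.5% ± 0.00839 in LENTI (4.54, 2.36 and 5.28 times IgG, n = 2), but its distribution in LENTI was not that of WT. At SWI/SNF sites 437 of 543 RING1B peaks fell in LENTI against KO and none rose by edgeR (median -1.93 against 0.14 elsewhere; camera adjusted p = 3.8e-56, and adjusted p = 0.00953 with an estimated correlation). On whole-library totals 255 fell and 10 rose (median -0.95 against 1.12). The HOXA cluster carried 157 ± 6.08 CPM in WT, 159 ± 1.57 in KO and 50.1 ± 1.51 in LENTI, with 11 of 12 peaks lower in LENTI and 9 on whole-library totals, and of HOX promoter peaks 13 of 15 fell, 8 on those totals. Developmental promoters had 28 falls and 2 rises of 43, which became 10 and 7 on whole-library totals. Single peaks that fell in LENTI lay 57.9 kb from WNT7B, a Wnt ligand (chromosome 22, 46035060 to 46036024, log2 change -4.77), and 10.5 kb from CBX8 (-4.55). An intronic RIMS1 peak (chromosome 6, 72356824 to 72358062) was at least 35.6-fold higher. In KO against WT, a RING1B peak between genes 549 kb from NEDD1 (chromosome 12, 97455795 to 97458345) rose by 3.49, 112 of 543 SWI/SNF-site peaks rose and 11 fell (median 0.28, -0.52 on whole-library totals; camera adjusted p = 2.86e-06, adjusted p = 0.086 with an estimated correlation). 3 of 15 HOX promoter peaks rose, none on whole-library totals, where 3 fell. PRC1 sites stayed near the other peaks in both comparisons (medians 0.08 and -0.05, or -0.72 and 0.93 on whole-library totals, where the other peaks moved alike; adjusted p = 0.339 and 0.512). The calls numbered 5824 up and 7544 down of 75204 in KO (700 and 28370 on whole-library totals, median -0.81; 8090 and 6172 with TMM on the 25% nearest IgG) and 8838 up and 10832 down in LENTI (40397 and 4647, median 1.11; 14098 and 9027; 3564 and 8738 with DESeq2). The KO count was 8138 without WT replicate 3 and 8246 without WT replicate 4.

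The PRC2 enzyme EZH2 gave little signal, with 1.25% ± 0.0338 of reads in its peaks in WT, 1.98% ± 0.00848 in KO and 1.24% ± 0.0145 in LENTI. An intronic SOX6 peak (chromosome 11, 16603250 to 16603679; SOX6 is a developmental transcription factor) fell by 2.99 in KO and rose by 2.51 in LENTI. In KO 20 of 12412 peaks rose and 298 fell by edgeR, and in LENTI 134 rose and 22 fell. On whole-library totals the calls were 1863 up and 109 down in KO (median 0.72) and 59 and 2077 in LENTI (median -0.69). DESeq2 called 3 up and 1 down in LENTI. In KO neither site set passed the threshold (camera on edgeR counts, adjusted p = 0.14 for PRC1 and 0.078 for SWI/SNF sites), and the direction turned with the scaling. PRC1 sites had 2 peaks up and 63 down (median -0.02), and 218 up and 24 down on whole-library totals (0.67), and SWI/SNF sites 0 and 6 (-0.12), and 32 and 2 (0.57). In LENTI SWI/SNF sites had a median of 0.16 (-0.50 on whole-library totals; adjusted p = 0.034, adjusted p = 0.0854 with an estimated correlation) and PRC1 sites 0.02 (-0.64 on whole-library totals; adjusted p = 0.399). PRC1 sites there had 19 peaks up and 2 down, and 5 up and 258 down on whole-library totals. The KO count was 154 without KO replicate 1 or 2, 167 and 202 without WT replicates 1 and 2, and the LENTI count 28 and 25 without KO replicates 1 and 2, 67 and 88 without LENTI replicates 1 and 2, and 360 and 331 without WT replicates 1 and 2.

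H3K27me3 left the same named loci in KO as in L307R and came back to some of them in LENTI. TENM3 held 1200 ± 27 CPM in WT, 54.8 ± 4.8 in KO (204 of 215 peaks lower) and 420 ± 12.7 in LENTI (158 higher than KO). SCN9A held 127 ± 6.66, 7.25 ± 0.131 and 126 ± 1.63 CPM, ZBTB18 174 ± 0.0685, 12.9 ± 0.286 and 36.8 ± 0.31, and EPHA4 399 ± 2.78, 35.4 ± 1.17 and 57.4 ± 1.89. SYK stood at 82.1 ± 2.94, 24.4 ± 1.52 and 23 ± 1.53 CPM, and SATB1, a chromatin organiser, at 166 ± 4.98, 55.8 ± 0.0862 and 43.6 ± 1.92, lower again in LENTI. A SMAD6 exonic peak (chromosome 15, 66702889 to 66705372; SMAD6 restrains BMP signalling) rose by 3.33 in KO. An intergenic peak 300 kb from CWH43 (chromosome 4, 49286702 to 49288440) was at least 202-fold higher in LENTI than KO. PRC1 sites had 786 rises and 2645 falls of 5776 in KO (median -0.24, camera on edgeR counts, adjusted p = 4.26e-07, adjusted p = 0.0697 with an estimated correlation) and a median of 0.06 in LENTI (adjusted p = 0.197), and SWI/SNF sites 107 and 44 of 264 in KO (adjusted p = 0.00592, adjusted p = 0.127 with an estimated correlation) and 12 and 109 in LENTI (median -0.56, adjusted p = 1.12e-12, and 0.0353 with an estimated correlation). Developmental promoters had 5 rises and 17 falls of 58 in KO. Of 156185 peaks, edgeR called 27894 up and 39122 down in KO (45231 and 32265 on column totals; 93052 and 19200 with TMM on the 25% nearest IgG, median 0.98) and 26425 up and 21973 down in LENTI (17387 and 44215 with TMM on the 25% nearest IgG).

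H3K27ac peaks held 28.5% ± 1.75 of reads in WT, 15.8% ± 0.148 in KO and 21.9% ± 0.284 in LENTI. The intergenic peak near SOCS6 was low in KO (chromosome 18, 70418431 to 70426120, 4.64 against 47.5 CPM, log2 change -2.59). In LENTI an intronic peak of CEMIP, a hyaluronan-binding protein (chromosome 15, 80848181 to 80854583), stood at 55.9 CPM against 4.28 in KO (log2 change 3.31, edgeR adjusted p = 4.35e-43), the peaks over CDH1, the junction protein E-cadherin, at 30.2 ± 0.993 against 10.2 ± 0.0121 (18.3 ± 0.233 in WT), and those over ACSL5, a fatty acid activating enzyme, at 52.8 ± 0.537 against 148 ± 3.8. An exonic RNF4 peak (chromosome 4, 2489045 to 2491396) rose by 2.35 in KO and fell by 2.21 in LENTI. At SWI/SNF sites 231 of 2401 peaks rose and 545 fell in KO (camera on edgeR counts, adjusted p = 0.0267, adjusted p = 0.0874 with an estimated correlation) and 627 rose and 185 fell in LENTI (adjusted p = 0.000471, adjusted p = 0.0535 with an estimated correlation), and at PRC1 sites 27 of 90 rose and 6 fell in KO (median 0.33, -0.44 on whole-library totals; adjusted p = 2.5e-05, and 0.0353 with an estimated correlation) and 6 rose and 21 fell in LENTI (median -0.20, 0.22 on whole-library totals; adjusted p = 0.0158, adjusted p = 0.0766 with an estimated correlation). Of 28854 peaks, edgeR called 3496 up and 4364 down in KO (5045 and 3384 on column totals; 458 and 20759 on whole-library totals, median -0.76) and 4462 up and 3245 down in LENTI (12924 and 640, median 0.41; 3172 and 6340 with TMM on the 25% nearest IgG). The KO count was 4818 without WT replicate 3 and 4792 without WT replicate 4.

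BAF155 rose over TENM3 in KO as it did in L307R, from 4.44 ± 0.605 to 24.5 ± 2.18 CPM with all 18 peaks up. It stood at 15.4 ± 1.57 in LENTI with 5 peaks down. Peaks near BMP5 (4.08), in an intron of RIMS2 (4.06) and in TENM3 (chromosome 4, 182578086 to 182579147, 3.84) rose most in KO, and a peak 9.7 kb from PPT1, a lysosomal thioesterase, fell by 2.24 in KO and rose by 2.21 in LENTI. In LENTI a peak 379 kb from ETS1, an ETS factor, rose by 2.61 and an intronic LAMB1 peak fell by 2.69. At PRC1 sites 51 of 270 BAF155 peaks rose and 2 fell in KO (median 0.27, -0.08 on whole-library totals; camera on edgeR counts, adjusted p = 2.81e-06, and 0.0169 with an estimated correlation) and the LENTI median was -0.14 (adjusted p = 0.0813). SWI/SNF sites had 436 rises and 181 falls of 5432 in KO (median 0.16, -0.19 on whole-library totals; adjusted p = 0.0267, and 0.00657 with an estimated correlation) and 180 and 143 in LENTI (adjusted p = 0.291, and 0.0211 with an estimated correlation). Of 54653 peaks, edgeR called 3783 up and 3347 down in KO (4785 and 2110 on column totals, 674 and 925 with DESeq2, 4459 and 2378 with TMM on the 25% nearest IgG, 2075 and 14814 on whole-library totals, median -0.36) and 1932 up and 2680 down in LENTI (2183 and 1964 on whole-library totals). The KO count was 3903 and 3944 without KO replicates 1 and 2 and 2959 and 3143 without WT replicates 3 and 4, and the LENTI count 2664 and 2314 without KO replicates 1 and 2 and 2564 and 2732 without LENTI replicates 1 and 2.

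Knockout raised several of the genes that rose in L307R and lowered hypoxia genes, a fall that rested on the 2 WT libraries and whose list call was lost with an estimated correlation (adjusted p = 0.291, camera on edgeR counts). TENM3 went from 0.189 ± 0.189 to 7.96 ± 0.71 CPM (n = 2 and 4; log2 change 5.41, edgeR adjusted p = 1.68e-07), DCLK1 from 6.41 ± 0.843 to 58.1 ± 1.51. SYK and EPHA4 rose by 2.54 each, the skeletal transcription factor RUNX2 (over SUPT3H) from 1.1 ± 0.0949 to 8.02 ± 0.507, the calcium sensor VSNL1 by 2.60, SATB1 by 3.11 and the phosphodiesterase PDE4D by 2.69. SCN9A, at 0 counts in WT, was at least 8.34-fold higher, a call lost without WT replicate 7 or 8, and LHFPL6 rose by 3.59 (7.85 without WT replicate 8). FANCF, of the Fanconi anaemia repair complex, fell from 7.52 ± 0.219 to 0.098 ± 0.0856 CPM (log2 change -6.13, edgeR adjusted p = 1.68e-07), ACSL5 from 77.5 to 7.1 CPM, the pseudokinase TRIB2 by 2.46, the dynein DNAH2 by 2.12 and ZNF426 by 1.85. Of 15150 genes, edgeR called 787 up and 957 down. A fit of only the KO and WT libraries called 4777. The WT arm had only 2 libraries, and the count was 287 and 199 without WT replicates 7 and 8 and 924, 873, 1107 and 1076 without KO replicates 1 to 4.

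Of 23 hypoxia genes 18 fell in KO (21 over the list alone; median -0.76, camera on edgeR counts, adjusted p = 5.82e-16, adjusted p = 0.291 with an estimated correlation), among them the glycolytic enzymes HK2 (-0.43) and PGK1 (-0.37) and the hormone ADM (-0.56), with 7 falls without WT replicate 7 and 4 without WT replicate 8. Stress response genes fell in 9 of 22 cases and rose in 1 (11 and 1 over the list alone; camera adjusted p = 5.91e-07, adjusted p = 0.291 with an estimated correlation), with the cystine transporter SLC7A11 down by 0.98, TRIB3 by 0.65 and CHAC1 by 1.11, and 5 falls without WT replicate 7 or 8. Immediate-early genes fell in 8 of 23 and rose in 1 (12 and 1 over the list alone; camera adjusted p = 7.96e-07, adjusted p = 0.291 with an estimated correlation), FOSL2 by 0.90 and EGR1 by 0.59, with 5 falls without KO replicate 1 and 4 without WT replicate 7 or 8. Epithelial junction genes fell in 7 of 24 and rose in 1 (9 and 2 over the list alone; camera adjusted p = 0.000483, adjusted p = 0.346 with an estimated correlation), CDH1 from 85.8 ± 0.073 to 54.9 ± 3.92 CPM, with 1 fall without WT replicate 7 or 8. Of 29 p53 targets 7 rose and 1 fell (12 and 4 over the list alone; camera adjusted p = 0.0157, adjusted p = 0.291 with an estimated correlation), BAX by 0.39, with 3 rises without WT replicate 7 and 1 without WT replicate 8. Wnt and stem genes had 5 rises and 2 falls of 17, BAMBI up by 1.13 and DKK1 by 0.71 (3 rises without WT replicate 7, 2 without WT replicate 8, and 3 and 1 without KO replicate 2). Mesenchymal genes had 1 rise and 4 falls of 16 (2 and 7 over the list alone; 2, 1, 1 and 2 falls without KO replicates 1 to 4, 1 without WT replicate 7 and none called without WT replicate 8). Developmental regulators had 4 rises and 1 fall of 46 (2 rises without WT replicate 7, 1 without WT replicate 8). HOX genes had 2 rises and 1 fall of 30, NF-kB genes 3 rises of 13, interferon genes 1 and 2 of 30, cholesterol genes 2 falls of 24, G2/M genes 1 fall of 30. Intestinal differentiation genes had CA2 up by 1.33 and KLF4 down by 0.70 of 3. SWI/SNF subunits had SMARCA2 up by 1.33 and 1 down of 26, PRC1 subunits 1 up and PHC2 down of 23, neuronal genes 1 and 1 of 10 and ribosomal genes 1 and 1 of 39. In the other 7 lists with measured members (PRC2, S phase, histone, small RNA, cancer-testis, fibroblast and blood cell genes, 62 genes) edgeR called 0, against 12 at an unadjusted p under 0.05 and 5 called by DESeq2. The S phase list had a median of 0.14 (camera adjusted p = 0.00626, adjusted p = 0.718 with an estimated correlation). Genes with PRC1 sites had 18 rises and 6 falls of 148 (camera adjusted p = 0.0157, adjusted p = 0.346 with an estimated correlation; again chosen on these cells' libraries) and those with SWI/SNF sites 69 and 90 of 944 (adjusted p = 0.678). H3K27me3 peaks lay at the starts of 8.51% of the rises, 3.15% of the falls and 4.29% of other genes, where silent genes again could only rise.

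**Figure D3:**
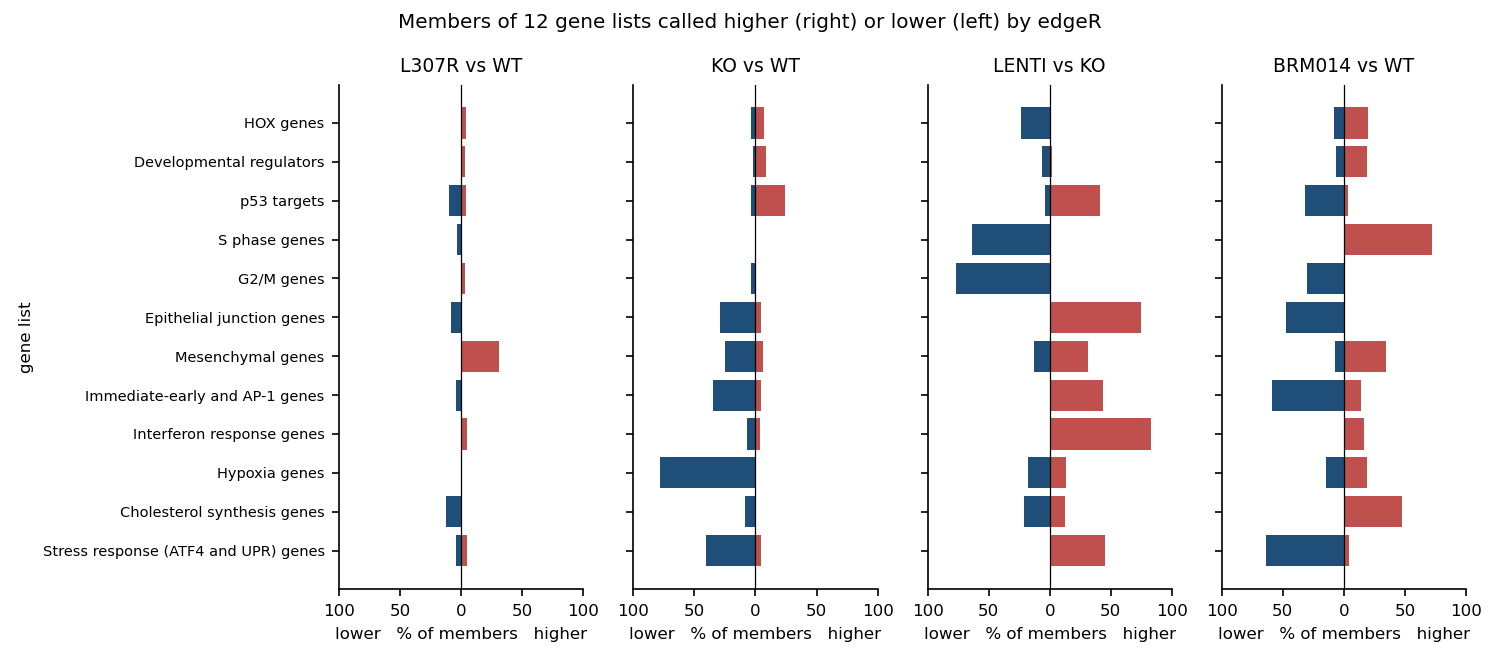
Percentage of the members of 12 gene lists that rose (right of 0) or fell (left of 0) by edgeR, one panel for each of the 4 RNA comparisons. Hypoxia genes had 18 falls in KO, interferon genes 25 rises in LENTI, and S phase genes 19 falls in LENTI and 21 rises with BRM014.

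LENTI cells differed from KO in epithelial junction genes, which rose. Interferon genes were higher and cell cycle genes lower, but their list calls were lost with an estimated correlation. CEMIP rose from 11 ± 1.31 to 159 ± 9.02 CPM (n = 4; log2 change 3.86, edgeR adjusted p = 8.33e-14), and SPTSSB, of sphingolipid synthesis, by 3.40. CREB3L3 rose by 2.18, GALNT5 by 2.06, PROM2 by 1.93, ATXN1 by 1.86 and LOXL4 by 1.81. VIM, the filament of mesenchymal cells, fell from 2.51 to 0.407 CPM, and DRD1 by 2.21. TNFSF18 fell from 13.9 to 3.45 CPM, DHRS2 by 1.82, DACT1 by 1.78, SUSD2 and DCLK1 by 1.58 and ITGB8 by 1.51. Epithelial junction genes rose in 18 of 24 cases (20 over the list alone; median 0.51, camera on edgeR counts, adjusted p = 1.34e-23, and 0.0376 with an estimated correlation), CDH1 by 1.19 to 125 ± 9.01 CPM and the protease ST14 by 1.15. Interferon genes rose in 25 of 30 (29 over the list alone; camera adjusted p = 9.23e-16, adjusted p = 0.148 with an estimated correlation), OASL from 2.91 ± 0.365 to 10.3 ± 3.33 CPM, IFIT2 by 1.61 and IFI6 by 1.39. Of 30 S phase genes 19 fell and of 30 G2/M genes 23 (27 and 28 over the lists alone; camera adjusted p = 9.61e-12 and 1.06e-15, adjusted p = 0.334 and 0.174 with an estimated correlation), for example UNG by 0.45, MCM7 by 0.31 and UBE2C by 0.36. HOX genes fell in 7 of 30 (camera adjusted p = 0.0201, adjusted p = 0.148 with an estimated correlation), HOXB8 by 0.47 and HOXB5 by 0.45. Immediate-early and stress response genes rose in 10 of 23 and 10 of 22 (14 and 13 over the lists alone; camera adjusted p = 1.74e-05 and 0.000119, adjusted p = 0.255 and 0.148 with an estimated correlation), EGR1 by 0.85 and TRIB3 by 0.72. Targets of p53 had 12 rises and 1 fall of 29 (camera adjusted p = 0.000187, adjusted p = 0.105 with an estimated correlation), CDKN1A by 0.63. Of 15150 genes, edgeR called 1712 up and 1431 down (2079 and 1094 on column totals; 1099 and 692 with the replicate number as a block; 6543 genes in all with LENTI replicates 1 and 2 alone). LENTI replicates 1 and 2 stood apart from 3 and 4. Chi-squared per degree of freedom was 1.88 and 1.93 within these pairs and 11 to 13.5 between them, against 2.12 to 3.05 among KO libraries. The 4 LENTI libraries may thus not be 4 independent ones, and the cause was not tested.

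Among the remaining lists in LENTI against KO, PRC2 subunits had 1 rise, JARID2 by 0.44, and 4 falls of 11, EZH2 by 0.31 (2 falls without any one of KO replicates 2 to 4, LENTI replicates 1 and 2 and WT replicates 7 and 8). Wnt and stem genes had 4 rises and 5 falls of 17 (3 falls without KO replicate 2 or 4), RNF43 down by 0.85 and AXIN2 by 0.99. Mesenchymal genes had 5 rises and 2 falls of 16, ZEB1 down by 0.96. Intestinal differentiation genes had 2 rises of 3, KLF4 by 0.80 (camera on edgeR counts, adjusted p = 0.017, adjusted p = 0.148 with an estimated correlation). NF-kB genes had 2 rises and 3 falls of 13, hypoxia genes 3 and 4 of 23, cholesterol genes 3 and 5 of 24, developmental regulators 1 and 3 of 46. SWI/SNF subunits had 1 rise and 2 falls of 26, PRC1 subunits 1 fall of 23, BCOR by 0.35, neuronal genes 1 and 2 of 10 and blood cell markers 1 rise of 1. In the other 5 lists (ribosomal, histone, small RNA, cancer-testis and fibroblast genes, 59 genes) edgeR called 0, against 4 at an unadjusted p under 0.05 and 0 by DESeq2. Genes with PRC1 sites had 16 rises and 16 falls of 148 and those with SWI/SNF sites 177 and 82 of 944 (adjusted p = 0.487 and 0.0759). TENM3 rose further in LENTI although its H3K27me3 was partly back, from 7.96 ± 0.71 to 25.5 ± 2.86 CPM (log2 change 1.68, edgeR adjusted p = 2.27e-07), and SCN9A rose by 1.39. FANCF stayed low, at 0.421 ± 0.0882 CPM against 7.52 ± 0.219 in WT.

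In experiment 3, with 3 libraries per group, the PHC2 signal in KO was again lower but stayed above IgG, at 16.6% ± 0.359 of reads (2.83 times IgG) against 27.8% ± 0.14 in WT and 30.1% ± 0.102 in LENTI. SWI/SNF-site peaks rose relative to the others in KO, 238 up and 14 down of 606 (median 0.80, 0.02 on whole-library totals; camera on edgeR counts, adjusted p = 6.42e-23, and 0.0058 with an estimated correlation). They fell in LENTI, 483 down and 1 up (median -1.78, -0.87 on whole-library totals; adjusted p = 1.07e-32, and 0.00657 with an estimated correlation). The HOXA cluster held 70.8 ± 5.75 CPM in WT, 105 ± 5.86 in KO (all 9 peaks up, 8 on whole-library totals) and 34.8 ± 1.22 in LENTI (all 9 down, 8 on whole-library totals). An exonic peak at the start of JARID2, a PRC2 cofactor (chromosome 6, 15244920 to 15248283), held 9.8 ± 0.585 CPM in WT, 32.8 ± 4.35 in KO and 3.94 ± 0.407 in LENTI (LENTI against KO -3.97, edgeR adjusted p = 1.78e-62). TENM3 held 1020 ± 16.8 CPM in WT, 1680 ± 66.3 in KO and 878 ± 9.43 in LENTI. An intergenic peak 996 kb from GRID1 (chromosome 10, 85369200 to 85370645) was, in KO, at least 11.3-fold below WT and 21-fold below LENTI. PRC1 sites passed the threshold in neither comparison (medians -0.05 in KO and 0.19 in LENTI, or -0.83 and 1.11 on whole-library totals, where the other peaks moved alike; camera on edgeR counts, adjusted p = 0.709 and 0.535). Of 68605 peaks, edgeR called 5081 up and 3870 down in KO (1717 and 30705 on whole-library totals, median -0.86) and 11826 up and 13574 down in LENTI (36557 and 5267, median 1.03; 7127 and 16530 with TMM on the 25% nearest IgG).

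PHC3, a paralog of PHC2, rose at SWI/SNF sites in KO relative to its other peaks. Of 939 SWI/SNF-site peaks 178 rose and 69 fell, but 97 rose and 101 fell on whole-library totals (median 0.43 and 0.22; camera on edgeR counts, adjusted p = 0.00181, and 0.012 with an estimated correlation). 6 of 13 HOX promoter peaks rose, 1 on whole-library totals. Over TENM3 PHC3 held 530 ± 14.4 CPM in WT, 1190 ± 26.5 in KO (66 of 104 peaks up) and 474 ± 11.4 in LENTI. An intronic TENM3 peak (chromosome 4, 181986603 to 181988133) rose by 2.95. An intronic peak of TUNAR fell by 3.36. The share of reads in peaks was 7.20% ± 0.0108 in WT, 6.10% ± 0.0329 in KO and 4.91% ± 0.0265 in LENTI. Of 22186 peaks, edgeR called 2928 up and 3358 down in KO (1649 and 4987 on whole-library totals, median -0.22; 1442 and 5386 with TMM on the 25% nearest IgG) and 1560 and 967 in LENTI (901 and 2234, median -0.29; 2470 and 596), where SWI/SNF sites had a median of -0.16 (adjusted p = 0.268) and PRC1 sites 0.23 (-0.03 on whole-library totals, with 63 up and 156 down; adjusted p = 0.0561, and 0.0353 with an estimated correlation; KO 0.311). The LENTI count was 1594 without KO replicate 2 and 1560 without KO replicate 3.

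EED, the PRC2 subunit that binds H3K27me3, gave too few reads in peaks to follow most sites, 11442 to 20281 per library (0.329% ± 0.00335 of reads in WT, 0.212% ± 0.00436 in KO and 0.194% ± 0.00429 in LENTI). Of 559 peaks tested, edgeR called 4 up and 10 down in KO, with 131 at an unadjusted p under 0.05, and 3 up and 1 down in LENTI, with 79. An intronic SOX2-OT peak (chromosome 3, 181301995 to 181303783) rose by 1.30 in KO (edgeR adjusted p = 0.0109), an intronic SLC4A4 peak fell by 1.54 in KO and rose by 1.72 in LENTI. A peak 180 kb from B3GAT1 rose by 2.28 in LENTI. The 18 SWI/SNF-site peaks had a median of 0.69 in KO (camera on edgeR counts, adjusted p = 0.0167, adjusted p = 0.0874 with an estimated correlation) and 0.05 in LENTI (adjusted p = 0.731), and PRC1 sites 0.05 and -0.03 (adjusted p = 0.709 and 0.557). On whole-library totals these medians were 0.36 and -0.105 at SWI/SNF sites and -0.285 and -0.185 at PRC1 sites. There 0 PRC1-site peaks rose and 18 fell in KO. DESeq2 called 1 peak in each comparison, down in KO and up in LENTI. The split was 2 up and 10 down in KO with RLE factors, 1 and 1 with TMM on the 25% nearest IgG, 4 and 5 on column totals and 1 and 60 on whole-library totals (median -0.32), and 3 and 8 on whole-library totals in LENTI. The KO count was 3, 6, 2, 4 and 7 without KO replicate 1, LENTI replicate 2, LENTI replicate 3, WT replicate 1 and WT replicate 3, and 0 without KO replicate 2 (162 at an unadjusted p under 0.05). The LENTI count was 1, 2, 10 and 11 without KO replicate 2, LENTI replicate 2, WT replicate 1 and WT replicate 2, and 0 without KO replicate 3 (98 at an unadjusted p under 0.05).

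Under BRM014, the share of SMARCC1 reads in peaks was 9.58% ± 0.77 against 8.31% ± 0.334 in WT (n = 3), and peaks changed in both directions. At SWI/SNF sites 509 of 3008 peaks fell and 227 rose, but 228 fell and 436 rose on whole-library totals (median -0.06 and 0.12; camera on edgeR counts, adjusted p = 0.237, and 0.0353 with an estimated correlation). An intronic peak of ERICH1 (chromosome 8, 628739 to 632285) rose by 1.56 (26.6 against 8.03 CPM, edgeR adjusted p = 9.85e-43) and an intergenic peak near BRD1 by 1.53, and a peak 48.9 kb from RB1CC1, an autophagy gene (chromosome 8, 52763385 to 52765034), fell by 2.50 and one 179 kb from the growth factor receptor FGFR2 by 2.09. HOX promoters had 4 rises of 17 and developmental promoters 5 of 21, and PRC1 sites a median of 0.26 (adjusted p = 0.291). Of 29684 peaks, edgeR called 3055 up and 4530 down (1751 and 5881 with TMM on the 25% nearest IgG; 5710 and 2494 on whole-library totals, median 0.22).

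PHC2 occupancy kept its level under BRM014, at 27.9% ± 0.0628 of reads, and changed at few peaks, 223 up and 770 down of 68605 by edgeR. SWI/SNF sites had 52 falls and 4 rises of 606 (median -0.16, camera on edgeR counts, adjusted p = 2.39e-06, and 0.00953 with an estimated correlation), and PRC1 sites a median of 0.07 (adjusted p = 0.0352, adjusted p = 0.107 with an estimated correlation). The HOXA cluster stood at 91 ± 2.19 CPM against 70.8 ± 5.75 in WT, with 2 peaks up. A peak 52.8 kb from NENF (chromosome 1, 212485753 to 212490455) fell by 2.66 (edgeR adjusted p = 2.05e-32), an intronic LRRC49 peak near LARP6 by 2.61. An intronic STK32B peak rose by 1.44. The count was 623, 538 and 635 without BRM014 replicates 1, 2 and 3.

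BRM014 changed RNA levels in both directions, with S phase and cholesterol synthesis genes up and stress response genes down. PLAU, the urokinase, fell to 29.6 ± 1.39 CPM (n = 3; log2 change -3.38, edgeR adjusted p = 7.7e-15), the stress cytokine GDF15 from 1730 ± 61.8 to 173 ± 23.5, the MAP kinase phosphatase DUSP5 from 1120 to 138 CPM. SLFN5 fell from 71.9 to 8.85 CPM, KLHDC7B by 5.16, IL20RB by 3.36, the hormone FGF21 by 3.32 and B3GALT5 by 3.15. The Wnt antagonist DKK1 rose from 239 ± 8.58 to 1020 ± 35.6 CPM (edgeR adjusted p = 1.54e-13), CCDC8 by 3.05, the splicing regulator NOVA1 by 3.01, IGFL2 by 2.53 and the receptor ERBB4 by 2.50. Other large changes rested on a single library each. ANG and PLEKHA2 were called higher and stood at -0.01 without BRM014 replicate 1 and -0.62 without BRM014 replicate 2. DNAJB5 was called lower and stood at 0.20 without WT replicate 3. Of 12566 genes, edgeR called 1016 up and 1319 down (1470 and 1000 on column totals).

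S phase genes rose in 21 of 29 cases under BRM014 (25 over the list alone; camera on edgeR counts, adjusted p = 1.03e-17, and 0.0176 with an estimated correlation), PCNA by 0.74 and FEN1 by 0.82. G2/M genes fell in 9 of 30 (camera adjusted p = 0.00383, adjusted p = 0.0936 with an estimated correlation), CENPA by 0.76. Stress response genes fell in 14 of 22 and rose in 1 (camera adjusted p = 1.91e-16, and 0.0246 with an estimated correlation), the chaperone HSPA5 by 1.29 and TRIB3 by 1.43. Immediate-early genes fell in 13 of 22 and rose in 3 (5 with DESeq2; camera adjusted p = 5.41e-07, and 0.0269 with an estimated correlation), ETV5 by 1.07, while EGR1 rose by 1.19. Cholesterol synthesis genes rose in 11 of 23 (camera adjusted p = 3.07e-08, and 0.0247 with an estimated correlation), INSIG1 by 1.29 and SQLE by 0.82. Of 28 p53 targets 9 fell and 1 rose (camera adjusted p = 0.000105, and 0.0477 with an estimated correlation), CDKN1A by 1.50 and BBC3 by 1.49. Epithelial junction genes fell in 11 of 23 (camera adjusted p = 4.15e-06, adjusted p = 0.0982 with an estimated correlation), ELF3 by 2.31 and CLDN4 by 1.48. Mesenchymal genes rose in 9 of 26 and fell in 2 (camera adjusted p = 0.0225, adjusted p = 0.49 with an estimated correlation), VIM up by 0.64, with 5 rises without BRM014 replicate 2, 3 without WT replicate 2 and 2 without WT replicate 3. NF-kB genes fell in 6 of 15 (camera adjusted p = 0.0149, adjusted p = 0.206 with an estimated correlation), LIF by 0.98. Developmental regulators rose in 9 of 48 and fell in 3 (camera adjusted p = 0.00304, adjusted p = 0.257 with an estimated correlation), SOX11 up by 1.23 and PITX1 down by 0.59, with 5 rises without BRM014 replicate 2 and 4 without WT replicate 2.

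Of 22 PRC1 subunits 6 rose and 3 fell under BRM014, CBX2 up by 0.92 and KDM2B by 0.68, and PHC2 down by 0.88 (3 rises without BRM014 replicate 2 or WT replicate 1, 2 without WT replicate 3). Of 10 PRC2 subunits 4 rose, EED by 0.46, and 1 fell, JARID2 by 0.41. Of 24 SWI/SNF subunits 4 rose, SMARCD1 by 0.53 (2 without BRM014 replicate 3, WT replicate 1 or WT replicate 2). HOX genes had 5 rises and 2 falls of 25, HOXB9 down by 1.19 (2 rises without BRM014 replicate 2, WT replicate 2 or WT replicate 3, 3 without BRM014 replicate 3). Interferon genes had 4 rises of 24 (2 without BRM014 replicate 3, WT replicate 2 or WT replicate 3, 1 without WT replicate 1). Hypoxia genes had 4 rises and 3 falls of 21, VEGFA down by 0.93 (1 rise without WT replicate 2 or 3). Wnt and stem genes had 2 rises and 2 falls of 16, SOX9 down by 0.97, neuronal genes 2 and 1 of 10. Fibroblast markers had 2 rises of 7 (camera on edgeR counts, adjusted p = 0.0288, adjusted p = 0.394 with an estimated correlation). Intestinal differentiation genes had 1 fall of 3, KLF4 by 1.86 (camera adjusted p = 0.0355, adjusted p = 0.2 with an estimated correlation), and histone genes 1 rise of 12. Ribosomal genes had 4 falls of 38, with 2 by DESeq2, 2, 5 and 8 without BRM014 replicates 1, 2 and 3 (6 rises besides without replicate 2) and none without WT replicate 2 or 3. In the other 3 lists (small RNA, cancer-testis and blood cell genes, 12 genes) edgeR called 0, against 1 at an unadjusted p under 0.05 and 0 by DESeq2. Genes with PRC1 sites had 9 rises and 9 falls of 122 and those with SWI/SNF sites 59 and 111 of 770 (adjusted p = 0.418 and 0.209). SMARCC1 peaks lay at the starts of 81.6% of the genes that fell, 66.3% of those that rose and 65.8% of the others (Fisher's exact test, falls against others, adjusted p = 2.88e-30).

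The perturbations shared calls to different degrees. L307R and KO shared 44 rises where independent lists would share 12.2 and 33 falls against 10.6, TENM3, DCLK1, SYK and EPHA4 among the rises, over 13261 genes tested in both. Opposite calls were above that level too, 23 up in L307R and down in KO against 14.4 and 12 the other way against 8.99. KO and BRM014 shared 201 falls against 97.2 and 112 rises against 58.2, and L307R and BRM014 46 falls against 16.6 and 21 rises against 15.7. L307R and LENTI shared more than independent lists in all 4 combinations, for example 45 rises against 25.5 and 37 falls in L307R that rose in LENTI against 18.8. LENTI against KO went against BRM014, with 393 genes up in LENTI and down with BRM014 where 170 would be shared, and 282 the other way against 107. Pearson's r of the log2 changes, across genes that are not independent replicates, was 0.158 for L307R with KO, 0.00304 for L307R with LENTI, 0.127 for KO with BRM014 and -0.18 for LENTI with BRM014. KO against WT and LENTI against KO share the KO libraries, which favours opposite calls. There 713 genes moved in opposite directions, 277 and 436 against 74.3 and 108 for independent lists. Observed r was -0.42, against -0.41 for groups simulated without change, and covariance -0.06 against -0.02. With the KO libraries split between the comparisons the means were -0.23 for r and 139.3 shared genes.

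**Figure D4:**
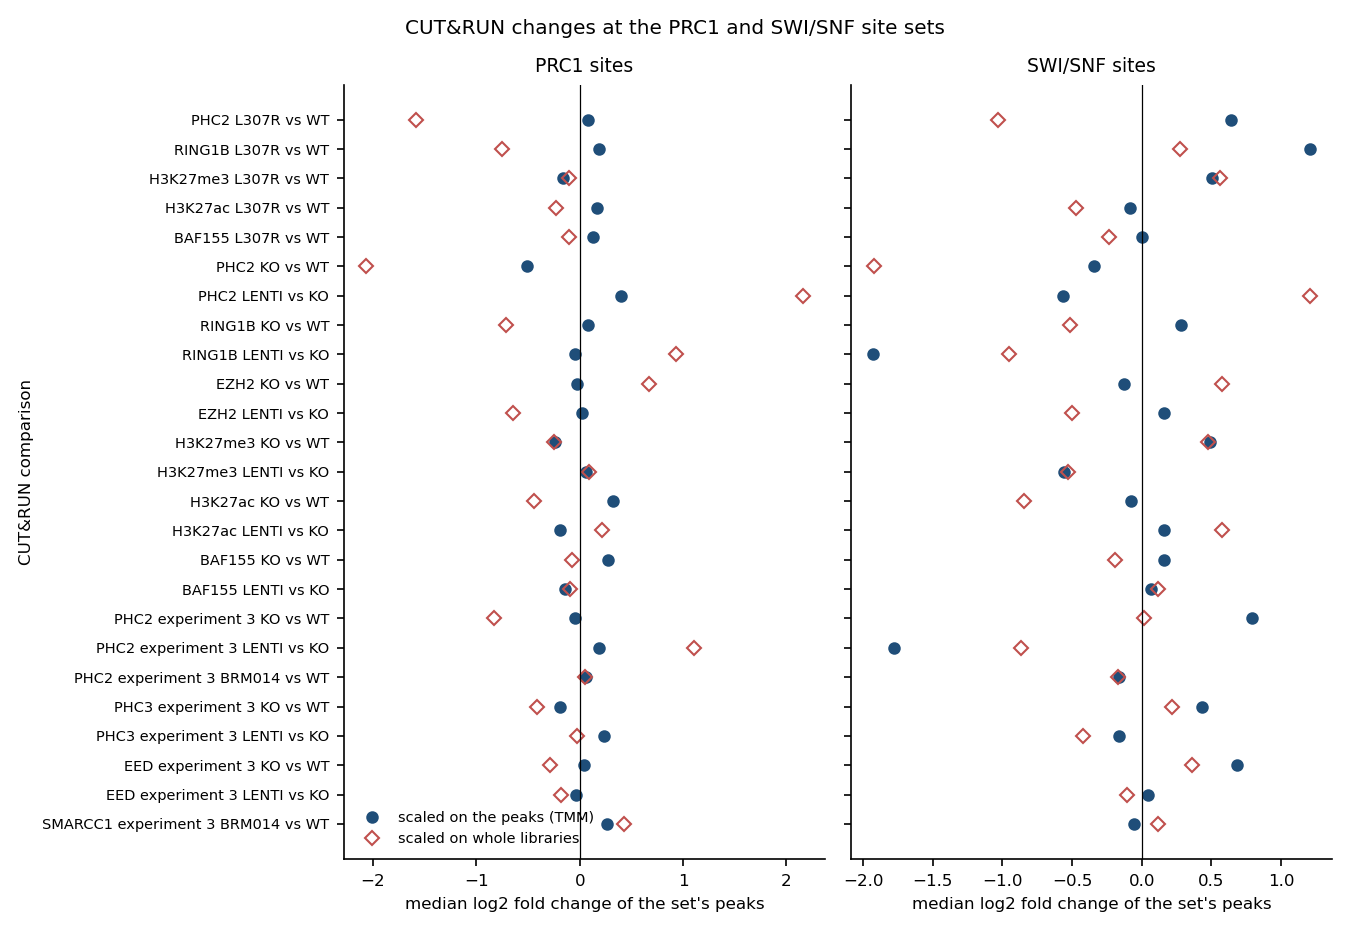
Median log2 change of the peaks at PRC1 sites and at SWI/SNF sites for each CUT&RUN comparison, scaled on reads in peaks and on whole-library totals. RING1B at SWI/SNF sites stood at 1.21 in L307R and -1.93 in LENTI against KO, and at 0.28 and -0.95 on whole-library totals.

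PRC1 and SWI/SNF sites seldom overlapped, and the peak lists of experiment 3 overlapped in part. The site sets were small, covering 4.97 and 2.79 Mb in experiment 1, and no chance level was computed. The low overlap therefore does not show that the 2 complexes occupy separate places. Of 7488 PRC1 sites in experiment 1 and 7606 in experiment 2, 49 (0.654%) and 82 (1.08%) met a SWI/SNF site. Of 36005 PHC3 peaks 71.3% overlapped a PHC2 peak by at least 1 bp, of 2700 EED peaks 83.9% did, and of 30080 SMARCC1 peaks 13.8%, while 29.1% of SMARCC1 peaks overlapped PHC3. The PHC2 list covered 154 Mb and the EED list 1.13 Mb.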

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

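In this part the tests of counting, of a change limited to L307R and the 3 on RING1B in LENTI were chosen after the result was seen, the others before. The L307R effect on RNA differed between replicates 1 to 3 and 4 to 6 for 895 of 15009 genes (interaction term, edgeR), 57 of them among the 375 called, for example TENM3 (87.1 CPM in L307R replicates 1 to 3 and 28 in 4 to 6, interaction -2.37) and ACSL5 (39.4 and 9.33 CPM, -1.83). The 2 sets stood apart in both genotypes, at 4789 of 14637 genes. Library size was excluded as the cause, since 90.1% of these stayed called after thinning to the smallest library, as was a different share of non-polyadenylated RNA, with medians of 0.057 for histone and -0.138 for small RNA genes. A change limited to L307R cannot account for the standing apart, since 3891 genes were called between the sets within WT alone, 119% of the 3280 within L307R. That count restates that both genotypes stood apart. It leaves open whether the 895 interaction genes changed in L307R alone. A difference in culture or preparation may lie behind the sets standing apart, though the labels put all 12 libraries in the same batch, and no biological explanation was tested.

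The PHC2 signal in KO libraries of experiment 3 stood above IgG, where that of experiment 2 did not, and the labels name the PHC2 antibody for experiments 1 and 2 only. The test of the way reads were counted could not decide. Its value, a share of reads in peaks 2.83 times that of IgG counted alike, is the pattern itself. Background at open chromatin may contribute, and was left open, with 24.6% of PRC1-site peaks higher in KO PHC2 than in KO IgG. An antibody also binding PHC3 may too, with PHC2 peaks over PHC3 peaks 0.225 higher than the others in KO against WT, and was left open. A biological explanation, PHC2 protein left in KO, has no separate test here. On whole-library totals 1717 peaks were called higher in KO than in WT and 30705 lower. Signal above WT in KO, as over TENM3 and the HOXA cluster, is not shown to be PHC2 protein.

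RING1B at SWI/SNF sites was lower in LENTI than in KO. Scaling on reads in peaks was excluded, since the median was -0.951 on whole-library totals. Less background at open chromatin of the kind IgG shows was excluded too, since the IgG log2 ratio was 0.0154. IgG does not show background of the RING1B antibody itself, so that was left open. PHC2 dose, the biological explanation, predicts that KO would be higher than WT. That prediction was left open, since KO against WT was -0.516 on whole-library totals and 0.28 on reads in peaks. Dose as read from PHC2 peaks would put LENTI near WT, as these held 22.8% ± 0.4 and 22.1% ± 3.13 of reads (n = 2). The LENTI titles name PHC2 overexpression, and a share of reads need not show a dose above WT. From KO to LENTI, RING1B moved by -1.93 on reads in peaks, far more than from WT to KO. On whole-library totals it fell in both steps. These values therefore do not decide on dose, and LENTI was not set against WT directly.

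Regrouping the RNA libraries of L307R and WT, 2 of 100 splits gave as many calls as the real one, itself included (375, highest other 1405, a split with L307R replicates 1, 2, 3 and 5 and WT replicates 2 and 3 on one side), and for RNA LENTI against KO 1 of 35 did (3143, highest other 0). These fits ignored the replicate sets that stood apart within L307R, WT and LENTI. The shares are therefore not a clean measure of what no change would give. The comparisons of 3 with 3 allow 10 splits, too few for a share under 0.05. In each only 1 split, the real one, reached its count, with a highest other of 0 (RNA BRM014 2335, PHC2 KO 8951, LENTI 25400 and BRM014 993, PHC3 KO 6286 and LENTI 2527, EED KO 14 and LENTI 4, SMARCC1 7585).

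Libraries the labels mark unused held signal above IgG, as a percentage of reads in peaks in L307R and WT: BAF155 10.2 and 11.3, H3K27ac 10.5 and 9.95, H3K27me3 46.3 and 44.1, PHC2 7.51 and 18.1, RING1B 11.4 and 20.5. PHC2 RNA stood at 83.2 CPM in unused WT replicate 9 and 74.6 in WT replicate 10.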

How the results depend on the processing

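RLE factors moved no count of calls by over 1.5 times (29 of 29 comparisons), column totals and no filter moved 2 of 29 each, the block 5 of 23, DESeq2 22 of 29 (26 lower, 3 higher), and leave-one-out fits 66 of 208, 2 of them to 0. Of the named values 604 of 607 kept direction and call with RLE factors, 583 with column totals, 565 with no filter and 533 with DESeq2, 4827 of 5317 leave-one-out values did and 4 reversed. The cause of the moves was not tested, except that leave-one-out fits have fewer samples. A lone library left in an arm is assumed to vary like the other groups. Depth left 559 EED peaks to test. Adding unused libraries was not run for the 12 comparisons of experiment 2, whose tables lack them. No paired analysis was possible because WT shares fewer than 2 numbers with KO in RNA and CUT&RUN of experiment 2, EZH2 aside. Same-number correlations elsewhere were -0.11 to 0.102. The block added calls for 20 of the named L307R genes and ended none there, and ended those of 19 named genes and peaks in other comparisons, 5 of them EED peaks.

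With DESeq2 the counts were RNA L307R 676, PHC2 L307R 789, RING1B L307R 7035, H3K27me3 L307R 48802, H3K27ac L307R 1636, BAF155 L307R 359, PHC2 KO 3200, RING1B KO 7347 and LENTI 12302. They were EZH2 KO 83 and LENTI 4, H3K27me3 KO 42746 and LENTI 27228, H3K27ac KO 4729 and LENTI 4777. BAF155 KO had 1599 and LENTI 1149, PHC3 KO 3763 and LENTI 1530, EED KO 1 and LENTI 1, SMARCC1 BRM014 3868, and 118 RNA calls shared by L307R and KO.

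With the replicate block they were RNA L307R 784, RNA LENTI 1791, PHC2 L307R 973, PHC2 LENTI 2208 and EED KO 3. With a term for replicates 1 to 3 or 4 to 6, RNA L307R had 1503, replicates 1 to 3 alone 1305 (H1-4 0.2031) and 4 to 6 alone 1864. With only KO and WT, RNA KO had 4777. LENTI replicates 1 and 2 alone gave 6543 (PHC2 gene 0.1264), and 3 and 4 alone gave MAGEA3 0.1386.

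On whole-library totals they were PHC2 L307R 30106, RING1B L307R 36328, H3K27ac L307R 7522, PHC2 KO 53458 and LENTI 58281, RING1B KO 29070 and LENTI 45044. EZH2 KO had 1972 and LENTI 2136, H3K27ac KO 21217 and LENTI 13564, BAF155 KO 16889, PHC2 of experiment 3 KO 32422 and LENTI 41824, EED KO 61 and LENTI 11.

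Unused libraries alone gave PHC2 645, RING1B 2233, H3K27me3 36101, H3K27ac 426 and BAF155 156, and reversed peaks of H3K27me3 near NEDD1 (-1.295), H3K27ac near BIN1 (-0.503), BSN (-0.1565), SOCS6 (0.1039) and CAV2 (0.3293), and BAF155 near NXPE1 (1.096), MTUS1 (0.3769) and HS3ST1 (0.05396). Added to the others, they gave RING1B 6323, H3K27me3 28757, H3K27ac 3, BAF155 32, and NXPE1 0.09028.

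TMM on the 25% of peaks nearest IgG gave H3K27ac L307R 6700, H3K27me3 KO 112252 and EED KO 2, column totals PHC2 KO 3461 and EED KO 9, and no filter EZH2 LENTI 386 and EED KO 81. With an estimated correlation, list tests passing numbered 3 for L307R (2 with the block, 4 with the replicate-set term), 0 for KO, 1 for LENTI and 5 for BRM014, and peak set tests 12.

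Leave-one-out ranges were RNA L307R 237 to 459, RNA KO 199 to 2530, PHC2 L307R 615 to 2898, RING1B L307R 8615 to 14469, H3K27ac L307R 2078 to 3557, BAF155 L307R 329 to 2134. PHC2 KO ranged over 2678 to 4930 and LENTI 2191 to 5206, RING1B KO 8138 to 11961, EZH2 KO 154 to 463 and LENTI 25 to 360. H3K27ac KO ranged over 4792 to 7845, BAF155 KO 2959 to 8146 and LENTI 2314 to 3982, PHC2 BRM014 538 to 1309, PHC3 LENTI 1560 to 2640, EED KO 0 to 18 and LENTI 0 to 11.

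In leave-one-out fits 4 named values reversed. ANG, BRM014 vs WT, was -0.006343 without BRM014 replicate 1 and 7.267 without BRM014 replicate 3. PLEKHA2, BRM014 vs WT, was -0.6205 without BRM014 replicate 2 and 6.458 without BRM014 replicate 3. DNAJB5, BRM014 vs WT, was 0.2043 without WT replicate 3 and -6.587 without WT replicate 1. In PTPRQ, chr12_80531151_80531889, PHC2 LENTI vs KO peaks, was 3.036 without KO replicate 2 and -7.357 without LENTI replicate 1.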

Other observations

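A peak of the EZH2 table inside PHC2, looked at after the values were seen, held 2494 and 1814 counts in the KO and 1693 and 1968 in the LENTI IgG libraries of experiment 2, and 7 and 8 in WT IgG. The EZH2 libraries held 1173 and 1172 counts there in KO, 925 and 980 in LENTI and 1091 and 1011 in WT.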
